A study of Drosophila melanogaster with 12 samples.

How the data were processed

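Egg ChIP-seq and input DNA of Drosophila ovarian somatic cells were available as 1 deposited table with a row for each RefSeq transcript (35327 rows) and for each transposon (175 rows) and 4 value columns, the inputs and Egg ChIPs of the siEGFP and siEgg cells. Per the labels, the deposited values are RPKM, reads scaled to row length and library size, and the submitters' processing notes give mapping with Bowtie2 2.2.4 to dm6. The columns carry no replicate number, so whether a column is 1 of the 2 labelled samples or a pool of both is unknown, and no siPiwi or siWde values were in the table. The planned design assumed replicated groups and a model with a replicate spread. Because the table has 1 column per group, that model left no residual degrees of freedom, and values with counting intervals were used in its place.

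Read counts were recovered from the deposited RPKM. Each column was scaled to whole reads, with row lengths anchored on the 5S rRNA genes of 135 bases. Within a tolerance of 0.0001 reads all 34762 rows with a value above 0 came out whole in every library, and 740 rows were 0 throughout. The recovered depths were 2183061 and 2293964 reads for the siEGFP and siEgg inputs and 1796866 and 1698148 for the ChIPs. These depths, the read counts, the widths of the intervals and the share of reads outside the table rest on that anchor, since whole reads fix only the product of length and depth. As a check, the recovered length equalled the genomic span of the gene in 4929 rows and exceeded it in 43. The recovery was tested on simulated data, where 96.5% of 3000 rows came out exactly, with 98.9% of the reads and 0% false. A row was matched to a gene by accession (34925 rows) or by symbol or synonym (35084 rows in all), with positions in dm6. Reads appeared to have been divided among the rows of a gene: the median siEGFP input per row was 6.24 RPKM for genes with 1 row, 3.43 with 2 rows and 1.74 with 5 rows, and after summing it was 6.37 with 2 rows and 7.53 with 5. Genes with 10 rows had 1.99 per row, or 1.15 with rows at 0 counted, and 10.3 after summing. Of these 215 genes, 161 had numbered copies of an accession, as 5S rRNA and histone genes do. The others had 1.03 per row and 8.13 after summing. The reads of all rows of a gene were therefore summed, a choice made after the structure of the table was seen.

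Enrichment was log2 of ChIP over input RPKM with a pseudocount of 0.6 RPKM, the median input divided by 10, and the change was enrichment in siEgg minus that in siEGFP. Genes and transposons with at least 10 reads in at least 2 libraries, and RPKM above the pseudocount in at least 2, were tested. A value was called when its log2 size was at least 1 and its 95% counting interval excluded 0. Intervals of ratios were exact (Clopper-Pearson on the split of reads between a pair of libraries), and those of changes used a normal approximation with 0.5 added to each count. A ratio with a library at 0 was bounded against a floor of 3 counts. No p-values were computed across genes, since 1 column per group gives no error between samples. Medians of lists and regions were placed as a percentile among 10000 random lists of the same size matched on reads in 10 levels, which describes their rank and is not a test between samples. Calls were tried on 20 data sets simulated with no effect and on simulated changes of 2-, 3-, 4- and 8-fold in 200 genes, 50 per size. These genes had at least 10 reads in all 4 libraries, which the filter did not require. By size, 50%, 94%, 100% and 100% of them were called enriched and 34%, 88%, 98% and 100% were called lower.

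Because genes called enriched are picked on the same siEGFP value that enters the change, 20 data sets with equal enrichment in both knockdowns (the mean of the ChIP rates of each gene) were simulated, and the siEGFP reads of input and ChIP were split at random 20 times, with calls made on the first part and changes measured on the second. Both were added after the values were seen.

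Chromosome 4, the pericentromeric ends of the arms (2L from 22 Mb, 2R to 6, 3L from 23, 3R to 4 and X from 22), Y, unplaced sequence and the remaining arms were compared as classes of genes. The 11 fixed lists were Egg machinery, somatic piRNA pathway genes, germline genes, somatic follicle cell genes, housekeeping, testis, neuron and muscle genes, transposons of the somatic piRNA pathway, other transposons and telomeric transposons. Not found under their list names were nos, rye, TART and TAHRE. The lists, the threshold, the pseudocount rule, the read filter and most alternatives were set before the data were examined. Named features were the 10 with highest siEGFP enrichment, the 10 with the largest fall and the 5 with the largest rise past the threshold, neighbours within 5 kb counting once, and every called member of the Egg, piRNA, germline and transposon lists. The rule on equal direction in both replicates could not be applied. Further features with many reads, gene families, piRNA cluster windows and transposons outside the lists were chosen after their values were seen.

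Alternatives were quantile scaling, a pseudocount 5 times smaller or larger, no filter, and a stricter call at a log2 size of 2 with a 99% interval. A further 4 were added after seeing the data: centring each comparison on the median gene, pooling both inputs, transcript rows as deposited, and at least 20 reads in each input. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Left out were the siPiwi and siWde comparisons, peaks, and intergenic regions, since the table has no values for them. Introns appeared to lie outside the rows as well. The recovered lengths of uex and AGO3, for instance, were 3936 and 2974 bases, far below their genomic spans. Values of genes with introns are therefore read as values of their transcript rows, although positions are given for the whole gene. Reads outside the rows of the table, 63.2% to 66.4% of each library, were counted in the depth alone.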

Results

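Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured the DNA bound by Egg, also called Eggless, in cultured ovarian somatic cells of Drosophila melanogaster. Egg is the fly SETDB1, an enzyme that methylates lysine 9 of histone H3. The labels list 12 samples in 8 groups, an input and an Egg ChIP for each of 4 knockdowns. Cells were crosslinked with formaldehyde 4 days into knockdown of EGFP (the control target), Egg, Piwi (the Argonaute protein that carries piRNAs into the nucleus) or Windei (Wde, a cofactor of Egg). The labels give 2 samples in each siEGFP and siEgg group and 1 sample in each siPiwi and siWde group. The table held 4 value columns, input and ChIP for siEGFP and for siEgg, without a replicate number, and the 4 siPiwi and siWde libraries were not analysed here. With 1 column per group, called a library below although it may pool both samples, there was no replicate spread, so each value is given with a 95% counting interval and each comparison is between libraries. The intervals cover counting error only, not differences between cultures or chromatin preparations.

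The input libraries held 2183061 reads for siEGFP and 2293964 for siEgg, and the ChIP libraries held 1796866 and 1698148. Rows of the table took 35.1% and 33.6% of the input reads and 36.8% and 34.6% of the ChIP reads. Transposon rows took 10.1% of the siEGFP input and 14.4% of the siEGFP ChIP, against 10.2% and 11.7% in siEgg. Of 16776 genes, 12559 had enough reads, as had 122 transposon rows, 6 of which represent elements of other Drosophila species. The median gene had 28 and 27 reads in the siEGFP and siEgg inputs and 20 in each ChIP, while the median transposon had 759.5 reads in the siEGFP ChIP.

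The siEGFP ChIP against its input asked which genes and transposons Egg occupies. The retrotransposon diver stood furthest above input among the transposons, with 40005 ChIP reads against 2176 input reads, an enrichment of 22.3-fold or 4.48 on the log2 scale (interval 4.42 to 4.54). The gene uex, at 2R:3900285-3949425 (dm6) next to the centromere, was enriched 17.2-fold (14.5 to 23.3) with 1156 ChIP reads. Its recovered row length was 3936 bases, so the value appears to cover its transcript sequence and not the introns of that span. CG17490, at 2L:22537668-22540597 beside the centromere, had a log2 enrichment of 3.58 (3.17 to 4.42). HeT-A, a retrotransposon that maintains fly telomeres, was enriched 2.30-fold, and the gypsy-family retrotransposon FBgn0000004, whose name is a number and which is given here by its identifier, was enriched 2.13-fold. In all, 715 genes were enriched at least 2-fold with an interval above 0, with a median log2 ChIP/input of 1.49 (quartiles 1.20 and 1.87), and 965 genes were depleted by the same rule. On data simulated with no effect, a mean of 88.8 genes (at most 104) met the rule for enrichment and 91.5 (at most 108) that for depletion. The median of all genes tested lay at -0.29, and centring on that median gave 1118 enriched and 238 depleted genes.

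Among the other genes of highest enrichment, most had few input reads. The noncoding RNA gene lncRNA:CR45201, at 4:959224-959434 on the small and largely heterochromatic chromosome 4, had 3 input and 68 ChIP reads, a ratio of 25.3-fold (9.03 to 137). lncRNA:CR44712 lies at X:21630908-21631433, inside the window of flamenco, the main source of piRNAs in ovarian somatic cells, and had 2 input and 51 ChIP reads, with a log2 ratio of 4.62 (3.03 to 8.04). RpS28-like had 11 ChIP reads and 0 input reads, at least 4.45-fold against a floor of 3 reads in the input library. The remaining genes of the highest 10 were lncRNA:CR45441 at 4.14, CG34132 at 4.15, CG40439 at 4.12, lncRNA:CR44209 at 3.99 and asRNA:CR45164 at 3.94 on the log2 scale. Of the genes with more reads, chosen after their values were seen, lncRNA:roX2, an RNA of the X-chromosome dosage compensation complex, went from 10 input to 126 ChIP reads, a log2 ratio of 3.72 (3.01 to 5.03). Genes beside or within the windows of the piRNA clusters flamenco, 20A and 42AB, also looked at afterwards, were not enriched apart from lncRNA:CR44712. DIP1 had 0.06 and Pld -0.30, and at 20A DIP-beta had 0.45, mst -0.68 and CG10918 -0.54, while lcs at -1.81 (-3.98 to -0.38) and lncRNA:CR45500 at -1.26 (upper bound -0.0011) lay below input on 4 and 6 ChIP reads.

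Genes on chromosome 4 and next to the centromeres of chromosomes 2 and 3 carried more Egg signal than genes on the arms. On chromosome 4, 24 of 86 genes were enriched (27.9%), and the median log2 ratio was 0.35, above all 10000 random gene lists matched on reads (percentile 100). The reads of all chromosome 4 genes together gave 0.54 (0.49 to 0.59). Enriched genes there included CG11076 at 2.83, Crk, an adaptor of receptor tyrosine kinase signalling, at 2.70, the zinc transporter gene Zip102B at 2.69, the ribosomal protein gene RpS3A at 2.27, the Polycomb-group gene pho at 1.83 and gw, which acts in microRNA silencing, at 1.11. Next to the centromeres, 53 of 212 genes were enriched (25%), again with a median of 0.35 at percentile 100, and their summed reads gave 0.81 (0.78 to 0.85). The X was an exception among them, with 1 of its 45 pericentromeric genes enriched and a median of -0.30. The borders of the class are approximate, so this may depend on where the X was cut. Of these X genes, 32 lay within 1 Mb of the border, with a median of -0.31, and the 13 beyond had -0.03. Without the X 52 of 167 pericentromeric genes were enriched (31.1%) with a median of 0.44. These included the ribosomal protein gene RpL5 at 2.29, CkIIalpha, the catalytic subunit of casein kinase II, at 2.26, lt, a gene long known to need heterochromatin, at 1.09, and AGO3, a germline Argonaute gene, at 1.43. On the remaining arms 629 of 12174 genes were enriched (5.17%), with a median of -0.31. The X arm had a median of -0.22 against -0.31 to -0.34 on the other arms, while 9 of 79 genes on unplaced sequence (11.4%) and none of 8 Y genes were enriched. With at least 20 reads required in each input the pericentromeric median was 0.21 and 25 genes were enriched.

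**Figure D1:**
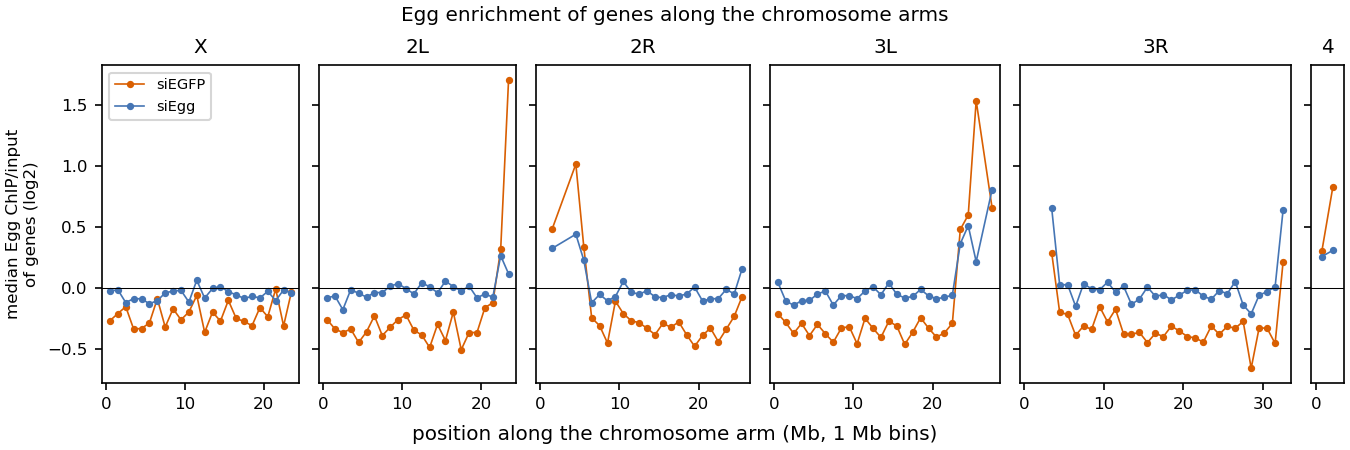
Median Egg ChIP/input (log2) of the genes in bins of 1 Mb along each chromosome arm (position in Mb), for siEGFP (orange) and siEgg (blue), in bins with at least 5 genes. In siEGFP the last bin of 2L reached 1.71 over 6 genes and a bin next to the centromere of 2R reached 1.02 over 16 genes, while the median over all arm genes was -0.31.

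Transposons as a class lay above genes in siEGFP, with a median log2 ratio of 0.19 against -0.29. In siEgg the medians were 0.17 and -0.04, so the median transposon hardly differed between the knockdowns. Intervals lay above 0 for 59 of the 122 transposons and below 0 for 15, against 48 and 27 with quantile scaling and 92 and 3 after centring. The count of enriched transposons was 5: diver, HeT-A, FBgn0000004, transib4 and transib1. transib4, at 1.14, and transib1, at 1.12, are DNA transposons. The 16 transposons known as targets of the somatic piRNA pathway had a median of 0.41, at percentile 98.9 of random transposon lists matched on reads (0.25 with quantile scaling and 0.71 after centring), and summed reads of 0.65 (0.63 to 0.67). Of these 16 elements, FBgn0000004 passed at 1.09 (1.03 to 1.15), gypsy fell just short of 2-fold at 0.97 (0.94 to 1.00) with 22908 ChIP reads, gtwin had 0.57, Stalker2 0.53, mdg1 0.47 and ZAM 0.03. The 10 other listed transposons had a median of -0.01 at percentile 5.35 (0.28 after centring), with diver the only enriched member. roo had -0.10 and the I-element had -0.85, while of the 3 telomeric elements listed HeT-A alone was found under its name. A row for TART of another species, Dyak\TART, had 0.16 (-0.15 to 0.49). With quantile scaling, FBgn0000004 had 0.92 and 2 transposons passed. After centring more passed, among them gypsy (1.27), S-element (1.23) and gypsy12 (1.12).

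Lists of genes fixed in advance gave few calls. Of 13 genes of the Egg machinery, HP1c, a heterochromatin protein 1 paralogue, was enriched at 1.36 (0.65 to 2.21). The median of that list was -0.06 at percentile 91.4, with HP1b at 0.83 and wde at 0.57. With quantile scaling the medians of the Egg machinery and of the somatic piRNA pathway genes flip to 0.06 and 0.08, while the median of all genes moved from -0.29 to -0.17. None of 15 somatic piRNA pathway genes was enriched, with a median of -0.05 at percentile 89.2, while shu, a co-chaperone gene of that pathway, was depleted at -1.05 and daed was depleted at -1.56 with 3 ChIP reads (interval -4.38 to -0.10). Both of these calls ended with quantile scaling (-0.84 and -1.31) and after centring. Of 15 germline genes tested, AGO3 and bgcn, a partner of the differentiation factor Bam, were enriched, bgcn at 1.42 (1.08 to 1.92), and the list median was -0.14 at percentile 81.8. Of 10 follicle cell genes none was enriched and the median was -0.42 (percentile 32.8). The lists used as contrasts had medians of -0.09 over 11 housekeeping genes (percentile 78.5), -0.32 over 8 testis genes (45.8), -0.62 over 5 neuron genes (8.81) and -0.30 over 5 muscle genes (58.2). In these contrast lists RpL32, a ribosomal protein gene, was the enriched member at 1.15.

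The siEgg libraries against the siEGFP libraries asked where the ChIP signal depends on Egg. The egg gene itself had log2 ratios of -0.68 in siEGFP and -0.01 in siEgg. These are DNA reads over the sequence of its transcript rows and do not measure its expression, so the depletion could not be checked from these data. The enrichment of diver fell from 22.3-fold to 5.09-fold, a log2 change of -2.13 (-2.22 to -2.04), while its input reads were 2176 and 2260. The enrichment of uex fell from 17.2-fold to 3.15-fold, a change of -2.45 (-2.95 to -1.95), and CG17490 fell by 3.19 on the log2 scale (interval -4.12 to -2.26) to 0.39. lncRNA:CR45201 fell by 3.93 (interval -5.95 to -1.90) and lncRNA:CR44712 by 3.03 (-5.36 to -0.70). Part of these falls came from the inputs, with 3 and 2 reads in siEGFP against 8 and 5 in siEgg. The ChIP compared without input changed by -2.66 and -1.97. lncRNA:roX2 went from 126 to 34 ChIP reads and fell by 2.30. Of the 715 genes enriched in siEGFP, 311 fell (43.5%). Genes picked for a high siEGFP value fall in part by counting error alone: in 20 simulations with no change between the knockdowns, a mean of 6.24% (at most 8.39%) of the enriched genes fell, and their median change was -0.40 (-0.47 to -0.34) against -1.19 in the data. To remove that counting error, the siEGFP reads were split at random into 2 parts, genes were called enriched on the first part and measured on the second. Both parts came from the same input and ChIP libraries, so a bias of these libraries stays in both. Over 20 splits the genes so picked had a mean median enrichment of 1.28 in the second part (1.22 to 1.34) and of 0.35 in siEgg, a change of -0.94 (-0.99 to -0.88). Among them, enriched genes next to the centromeres changed by -1.11 (-1.30 to -0.89) and those on chromosome 4 by -1.15 (-1.50 to -0.98). For the simulations and splits, brackets give the lowest and highest of the 20 runs and are not counting intervals. The ratios of all genes also spread less in siEgg (standard deviation 0.48 against 0.75). Genes depleted in the first part likewise went from -0.62 in the second part to -0.13 in siEgg. The split therefore cannot decide whether the fall of the enriched genes depends on Egg. In siEgg 164 genes were enriched, 71 of them also in siEGFP.

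Over all genes tested the median change was 0.22, but 0.01 with quantile scaling and 0.13 with pooled inputs. By the same rule 426 genes fell and 643 rose in siEgg, and 343 of those that rose had been depleted in siEGFP, 35.5% of the depleted genes, where the simulations with no change gave a mean of 8.43% (at most 11.1%). Genes depleted in the first part of the split siEGFP reads had a median of -1.47 there but -0.62 in the second part, and a median change of 0.48 from the second part (lowest 0.44 and highest 0.52 of the splits). Genes not enriched in the first part had a median change of 0.25. The simulations held no such shift, with a median change of 0.02 for genes not enriched. The shares of 35.5% and 8.43% therefore do not separate a rise particular to depleted genes from the shift of all genes. The rule called a mean of 148 falls (at most 189) and 153 rises (at most 175) on simulated data with no effect. Which direction was more frequent depended on the processing. Rises made up 60.1% of the changed genes, but 46.0% with quantile scaling (443 falls and 378 rises), 28.2% after centring on the median gene (708 and 278) and 42.6% with both inputs pooled (602 and 446), where 293 of the 426 falls were kept. The share was 30.3% with the pseudocount 5 times larger and 69.9% with at least 20 reads in each input. The ChIP libraries compared without their inputs gave 615 lower and 529 higher genes. The inputs differed from each other by a standard deviation of 0.335 over 8436 genes with at least 40 reads, where counting alone gives 0.334, and 44 genes were higher and 138 lower in the siEgg input.

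**Figure D2:**
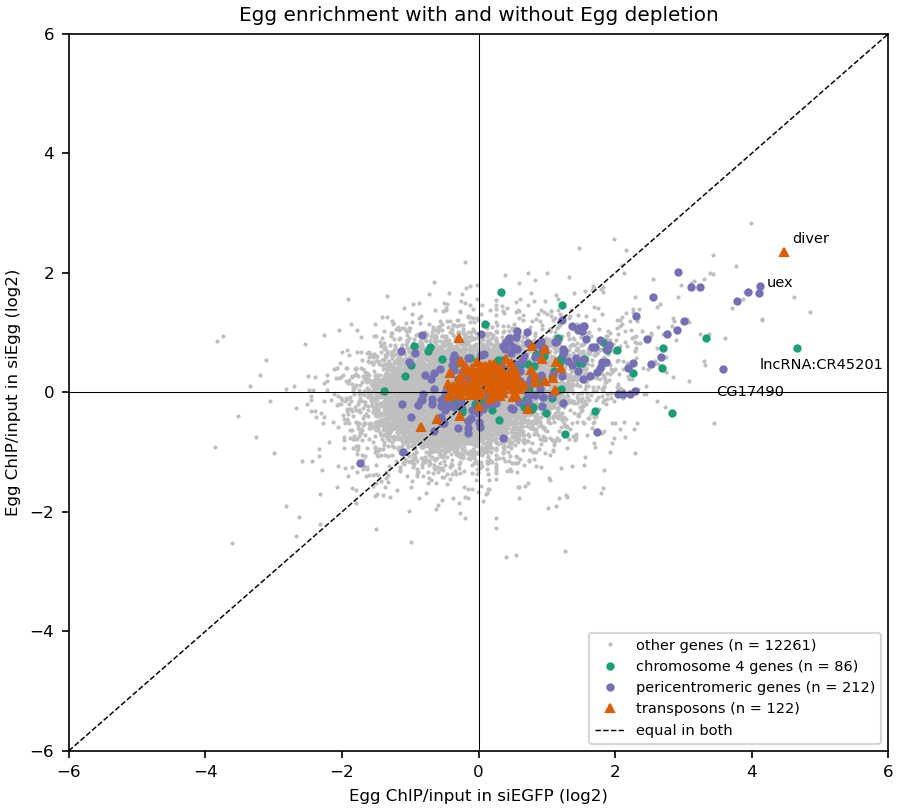
Egg ChIP/input (log2) of each gene and transposon in siEGFP (horizontal) and siEgg (vertical), with the line of equal values dashed. diver lies at 4.48 and 2.35, uex at 4.10 and 1.65, and genes outside chromosome 4 and the pericentromeric regions are in grey.

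The largest falls among genes were those of CG3448 (-3.96), lncRNA:CR43631 (-3.93), COX7C (-3.47), l(3)neo43 (-3.42), l(2)SH0834 (-3.30), CG42688 (-3.27), CG11076 (-3.17) and CG12546 (-3.16), beside lncRNA:CR45201 and CG17490. COX7C encodes a subunit of cytochrome c oxidase, and its change had an interval of -5.32 to -1.63, with 8 and 20 input reads. CG3448 had 2 reads in the siEGFP input and 16 in the siEgg input, and with both inputs pooled its change was -1.65. Falls resting on more reads, picked after their values were seen, included isoQC, a glutaminyl cyclase gene, from 1302 to 469 ChIP reads (change -1.48, interval -1.70 to -1.26), RpL5 from 241 to 63 (-2.27) and Zip102B from 182 to 42 (-2.29). The histone gene His4:CG33869 went from 411 to 78 ChIP reads (-2.47), summed over 9 rows of near-identical histone copies that share reads. The largest rises were those of lncRNA:CR45450, CG14500, Sfp65A (3.65), Cpr66Cb (3.50) and lncRNA:CR43855 (3.47, 3 ChIP reads in siEGFP, interval 1.17 to 5.78). lncRNA:CR45450 had 0 reads in the siEGFP ChIP against 12 in its input, at least 3.29-fold below input, and CG14500 had 0 against 11, at least 3.02-fold below, each against a floor of 3 reads in that library. Sfp65A and Cpr66Cb each had 1 read in the siEGFP ChIP, with intervals of 0.95 to 6.34 and 0.87 to 6.13. With the pseudocount 5 times larger the calls at lncRNA:CR45450, CG14500, Sfp65A and Cpr66Cb ended, and with pooled inputs that at lncRNA:CR43855 ended at 1.61.

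Genes of chromosome 4 and of the pericentromeric class, the X apart, had lower values in siEgg as groups. On chromosome 4, 15 genes fell and 7 rose, 13 of the falls being among the 24 enriched genes. The median change there was -0.19, below all random lists matched on reads, and remained negative with quantile scaling (-0.26) and after centring (-0.41). These lists were not matched on siEGFP enrichment, which enters the change, so a class high in siEGFP tends to rank low. Relative to the median gene, the chromosome 4 median was 0.65 in siEGFP and 0.31 in siEgg. Next to the centromeres 28 genes fell, 27 of them enriched in siEGFP, and 2 rose, with a median change of -0.08 that was again below all random lists, and of -0.08 with quantile scaling and -0.30 after centring. Relative to the median gene, the median of the pericentromeric class was 0.64 in siEGFP and 0.30 in siEgg. The 45 X genes of that class had a median change of 0.29 and the other 167 had -0.22. Part of the signal stayed in siEgg, where the summed reads gave 0.23 on chromosome 4 and 0.34 next to the centromeres. On the remaining arms 380 genes fell and 633 rose with a median change of 0.23.

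The median change of all transposons was -0.02, but 0.29 with quantile scaling and -0.24 after centring. Among transposons diver, transib1 and the LINE element G6 fell and Bari2 rose. transib1 fell by 1.08 to 0.04 while its input was higher by 0.83, and G6 fell by 1.00 (interval -1.32 to -0.69) to -0.28. Bari2, with 18 siEGFP and 30 siEgg ChIP reads, rose by 1.19 (0.03 to 2.35). With quantile scaling transib1 had -0.53 (-1.12 to 0.06) and G6 had -0.66, so that diver alone still fell, and the rise of Bari2 ended after centring, at 0.97 (-0.20 to 2.13), and with pooled inputs. After centring FBgn0000004 (-1.07), HeT-A (-1.02) and gypsy (-1.01) passed the rule for a fall as well. Smaller differences had narrow intervals: FBgn0000004 changed by -0.85 (-0.94 to -0.76), HeT-A by -0.80 and roo by 0.45 (0.40 to 0.50). In total 30 transposons had an interval of the change below 0 and 31 above 0, against 15 and 61 with quantile scaling and 58 and 9 after centring. Under the 3 scalings alike, 13 transposons lay below 0, among them diver, G6, FBgn0000004, HeT-A and gypsy12, and 9 lay above 0, among them roo, Transpac (0.52), Bari1 (0.53) and FB (0.59). The values of gypsy, -0.79, and springer, -0.59, were not of that kind: with quantile scaling they were 0.04 and 0.55. After centring they were -1.01 and -0.81. Quantile scaling sets values by rank, and springer lay below diver in the siEGFP ChIP (2340 against 3643 RPKM) but above it in siEgg (1493 against 823). The quantile values of gypsy and springer, near the top ranks, therefore do not show whether their signal fell.

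**Figure D3:**
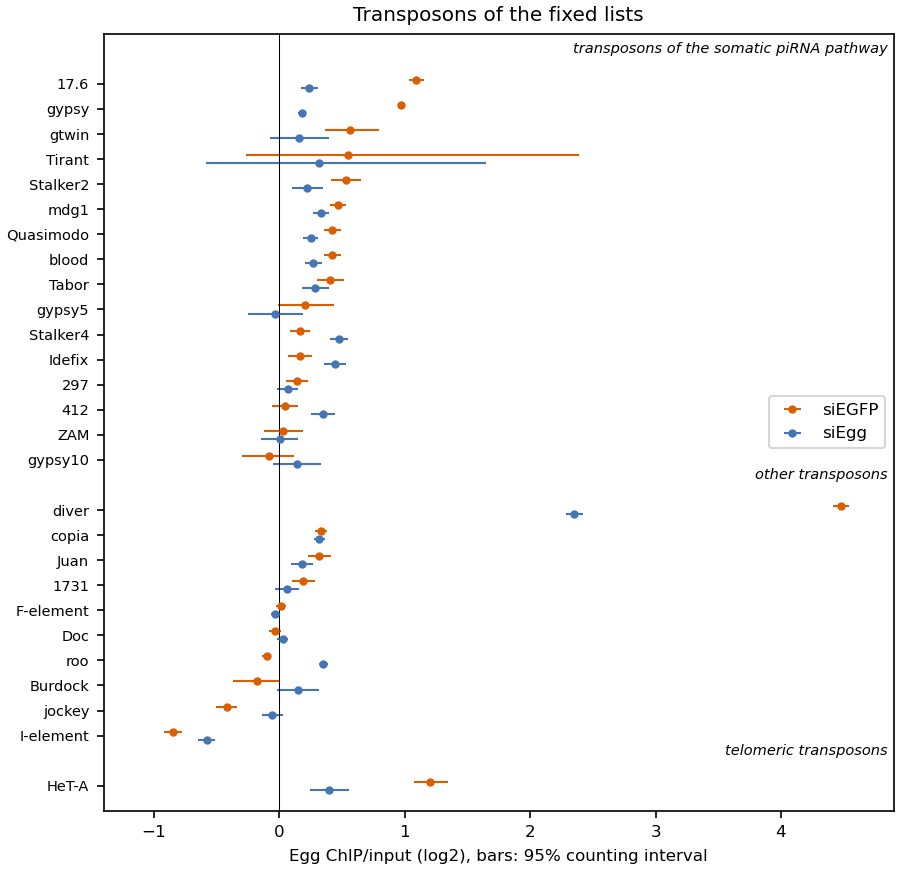
Egg ChIP/input (log2) of the listed transposons in siEGFP (orange) and siEgg (blue), with bars for the 95% counting interval. diver went from 4.48 to 2.35, FBgn0000004 (the top row, drawn under its name) from 1.09 to 0.24 and HeT-A from 1.20 to 0.40. gypsy went from 0.97 to 0.18, a difference of 0.04 with quantile scaling, which sets values by rank.

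Of the fixed lists, the transposons of the somatic piRNA pathway had a median change of -0.14 at percentile 11.2 with no member past the rule, and the median flips to 0.15 with quantile scaling. The other listed transposons had 0.02 at percentile 74.5, with diver the member that fell. The Egg machinery genes had a median change of -0.03 at percentile 8.34 and no call on the change, although in the ChIP compared without input HP1c and HP1b were lower. The somatic piRNA pathway genes had 0.19 (percentile 44.5), with a rise of 1.38 (0.21 to 2.55) at fs(1)Yb, a gene required for piRNA production in somatic cells, and with zuc lower in the ChIP alone. Among germline genes bgcn fell by 1.20 (interval -1.88 to -0.52; -0.98 with quantile scaling, no longer past the rule) and tej, which encodes a Tudor-domain protein of the germline piRNA pathway, rose by 2.65 (1.32 to 3.98; 1.61 in the ChIP without input, the input having gone from 36 to 17 reads), and the list median was 0.36 (percentile 75.5). zfh1, a transcription factor of somatic gonad cells, rose by 1.01 among the follicle cell genes, whose median was 0.23 (percentile 46.3). can, a testis-specific TAF, rose by 1.33 among the testis genes, whose median was 0.34 (percentile 66.3). The medians of the housekeeping, neuron and muscle genes were 0.21 (percentile 51.2), 0.60 (95.1) and 0.35 (62.7), with no member called. After centring on the median gene the calls at fs(1)Yb and zfh1 ended at 1.16 and 0.79, and the list medians of the Egg machinery, somatic piRNA pathway and housekeeping genes were -0.25, -0.04 and -0.01.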

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

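The comparison of signs in the 2 knockdowns was chosen after the values were seen, and no difference between groups was tested, since each group had 1 value column. Of 151 features named by a rule or on a fixed list, 7 had log2 ChIP/input on opposite sides of 0 in siEGFP and siEgg with both counting intervals excluding 0. Transposons reported outside these were not counted. Of those, G6 (0.72 and -0.28), springer (0.55 and -0.04) and Transpac (-0.27 and 0.26) also switched side with both intervals excluding 0. FB (-0.44 and 0.14) had values of opposite sign too. Of the 7, below input in siEGFP and above it in siEgg were tej at -1.52 and 1.13 (change 2.65), betaTub56D, a beta-tubulin gene, at -1.72 and 0.93 (2.65), BBS1, a gene of ciliary transport, at -1.21 and 1.06 (2.27) and the retrotransposon roo at -0.10 and 0.35 (0.45). Above input in siEGFP and below it in siEgg were lncRNA:CR43631 at 1.27 and -2.66 (change -3.93), COX7C at 1.79 and -1.69 (-3.47) and His4:CG33869 at 1.96 and -0.52 (-2.47). Part of these changes came from the inputs: from siEGFP to siEgg the input of BBS1 changed by -1.35, of tej by -1.04, of betaTub56D by -0.84 and of COX7C by 1.14, and the ChIP compared without input changed by 0.92, 1.61, 1.80 and -2.33. In the siEgg ChIP lncRNA:CR43631 had 1 read and COX7C had 4, and tej and betaTub56D each had 9 reads in the siEGFP ChIP. Under other scalings the switch of side was lost for 3 of the 7. After centring on the median gene roo lay above 0 in both knockdowns, at 0.19 (0.15 to 0.23) and 0.39, and with quantile scaling the siEgg interval of His4:CG33869 (-0.72 to 0.09) and the siEGFP interval of lncRNA:CR43631 (-0.08 to 2.46) included 0.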

How the results depend on the processing

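The alternatives of quantile scaling, pseudocount, filter and stricter call were planned. Centring on the median gene, pooled inputs, transcript rows as deposited and at least 20 reads in each input were chosen after seeing the data. No called value of a named feature changed sign under quantile scaling, the other pseudocounts, centring, pooled inputs or the filter of 20 reads. Named features were not checked under the other alternatives. Medians of lists did change sign with quantile scaling, as for the Egg machinery (-0.06 to 0.06) and the change of the transposons of the somatic piRNA pathway (-0.14 to 0.15). The median enrichment of all genes also moved with that scaling, from -0.29 to -0.17. Of 370 values of named features, 354 stayed within their counting interval, 16 moved outside it, and 33 calls ended, among them those of fs(1)Yb, shu, daed, CG40439, lncRNA:CR45450 and CG14500 under at least 1 alternative, and FBgn0000004 (0.92) and bgcn (-0.98) with quantile scaling. Of 154 list medians 9 moved beyond their interval. With no filter, the smaller pseudocount or transcript rows as deposited, every count of calls compared stayed within 1.5 times. With transcript rows as deposited, transposons and the classes of genes by chromosome were not compared. For the values that moved by more, the cause was not tested, except that the stricter call and the filter of 20 reads pass fewer genes by construction (7670 genes tested with the filter) and a larger pseudocount shrinks ratios of low RPKM.

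With quantile scaling 328 genes were depleted, 378 rose, 196 were enriched and fell, and of the transposons 2 were enriched, 1 fell and 5 rose, with 1 lower and 8 higher in the ChIP alone. Of the genes enriched with quantile scaling, 529 of 533 were also enriched without it. With the pseudocount 5 times larger, 282 genes were depleted, 186 fell, 81 rose, 178 were higher in the ChIP alone, 157 were enriched and fell, and 15 were enriched on chromosome 4; 3 transposons were enriched, 1 fell and 0 rose. The stricter call left 143 enriched and 49 depleted genes, 68 that fell and 42 that rose, 70 lower and 34 higher in the ChIP alone, 43 enriched and fallen, 7 enriched on chromosome 4 and 22 next to the centromeres; 1 transposon (diver) was enriched, 1 fell, 0 rose and 1 was lower in the ChIP alone.

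Centring on the median gene gave 1118 enriched and 238 depleted genes, 708 that fell and 278 that rose, 229 higher in the ChIP alone and 537 enriched and fallen; 13 transposons were enriched, 6 fell and 0 rose. The median enrichment and change became 0.65 and -0.41 on chromosome 4 and 0.64 and -0.30 next to the centromeres. With both inputs pooled 0 transposons rose, and 602 genes fell and 446 rose. With at least 20 reads in each input 202 genes were enriched, 626 depleted, 183 fell and 425 rose, 189 were lower and 289 higher in the ChIP alone, 116 were enriched and fell, and 11 on chromosome 4 and 25 next to the centromeres were enriched, where the median was 0.21.

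No paired analysis was possible because the replicate numbers 1 and 2 of the labels are not carried by the value columns. Not run, for want of replicate columns or of siPiwi and siWde values, were the replicate block, leaving out replicates, count models, replicate agreement, the siPiwi and siWde comparisons with a pooled spread, siWde against siPiwi, the overlap of losses, and tests of classes with p-values. An alternative with the siEGFP and siEgg libraries alone is the calculation reported. Overlap of peaks at 50%, gene flanks, promoters and intergenic classes were not run because the table holds transcripts and transposons. Depth limited single genes, with a median of 20 ChIP reads. Among genes with at least 10 reads in all 4 libraries, a simulated 2-fold fall was called in 34% and a 4-fold fall in 98%. Genes with fewer reads in a library, which the filter let pass, were not changed in that simulation.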

Other observations

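The gene families below were chosen after their values were seen, as were 7 of the 10 tests, all except those on reads drawn off by transposons and enriched genes, on short rows and on neighbouring genes. Cytoplasmic ribosomal protein genes, which lie scattered over the genome, carried Egg ChIP signal in siEGFP: 22 of 66 were enriched (33.3%), with RpL34b at 2.41 and RpS5b at 2.31, a family median of 0.69 and a median change of -0.43 in siEgg (-0.40 with quantile scaling, -0.65 after centring). Genes of the mitochondrial respiratory chain had 19 of 62 enriched (30.6%), with UQCR-Q at 3.60 and ATPsynE at 3.05, a median of 0.60 and a median change of -0.39 (-0.43 and -0.61). Genes of the mitochondrial ribosome had 11 of 50 enriched, with mRpL27 at 3.30, a median of 0.32 and a median change of -0.39 (-0.30 and -0.61). Each of these medians of enrichment exceeded all 10000 random lists matched on reads, and each median change lay below all of them. The lists were not matched on siEGFP enrichment, which enters the change.

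Among the replication-dependent histone genes, whose near-identical copies share reads, the summed reads of the 21 His4 copies gave 1.10 (0.98 to 1.22) in siEGFP and -0.05 in siEgg, and those of the 23 His3 copies gave 0.37 and 0.03. The His1, His2A and His2B copies gave -0.26, -0.36 and -0.37 in siEGFP. The median change of the His4 copies was -0.55, but -0.05 with quantile scaling, and that of the His3 copies flips from -0.29 to 0.21. Genes of chemosensory receptors, which act in sensory neurons, lay low in siEGFP, with 30 of 173 depleted, a median of -0.48 at percentile 0.01 and a median change of 0.45 at percentile 99.9 (0.10 with quantile scaling, 0.23 after centring). Cuticular protein genes had a median of -0.60, with 7 of 44 depleted and none enriched, and a median change of 0.38 (0.07 and 0.15). Antisense RNA genes, whose reads are shared with the genes they overlap, had 25 of 161 enriched and 14 depleted. Of 595 lncRNA genes 56 were enriched and 51 depleted, with a median of -0.27 (percentile 70.0) near that of all genes.

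diver stood 22.3-fold above input in siEGFP and fell in siEgg. A lower copy number in the siEgg cells was argued against by its input reads, which differed by -0.0168 (log2). An amplified pile-up in the siEGFP ChIP alone was argued against as the whole source of the enrichment by the ratio of 2.35 in the separate siEgg ChIP. That ratio cannot exclude a part of it in the fall from 40005 to 8538 ChIP reads. Reads of the related element diver2 counted as diver stay open, since they would be missing from the diver2 row, where the reads left gave 0.29 in siEGFP. A difference between chromatin preparations stays open too, with 1 column per group, beside binding of Egg to diver, which may account for the fall as a hypothesis.

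The median gene lay at -0.29 in the siEGFP ChIP and the spread of genes was 0.75, against 0.48 in siEgg. Without the reads of transposons and enriched genes the median was still -0.19, so reads drawn off by these may account for -0.10 of it and not for the whole. A shallower library was argued against by the siEgg ChIP, the shallowest, where the median was -0.0367. More reads outside the rows of the table were argued against by a difference of -1.70 percentage points between siEGFP ChIP and input. GC content, for which no genome sequence was used, stays open, and no biological explanation was tested.

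The 128 ribosomal protein and respiratory chain genes, 41 of them enriched, had a median of 0.67 in siEGFP. Recovery of these genes in any ChIP was examined by the median change of -0.40 in siEgg, below the random range of 0.04 to 0.39. That rank cannot decide it, because the families were chosen after their siEGFP values were seen, and these values enter the change. The random lists were not matched on siEGFP enrichment, and the ratios of all genes spread less in siEgg (0.48 against 0.75). The siEgg median of the families, 0.11, was lower than in siEGFP but still at percentile 99.4. Short rows were argued against by random lists matched on length, whose median was -0.19 and among which the families stood at percentile 100. A bias of the siEGFP ChIP library as a whole, such as in open chromatin of active genes, cannot be told apart from binding by Egg with 1 ChIP column per knockdown.

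A hypothesis that enriched genes lie in groups along the arms was tested and not borne out: 46.6% of the 629 enriched arm genes had another enriched gene at 5 to 50 kb, within the 40.5% to 50.2% of 1000 random sets.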
